A study of Nannochloropsis oceanica with 15 samples.

How the data were processed

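Gene expression was measured by RNA sequencing of total RNA from Nannochloropsis oceanica IMET1 at 0, 6, 12, 24 and 48 h, with 3 libraries per time and 15 in all. Each library was assigned to its time from its label. The labels mention triplicate cultures, and nothing says whether a letter (a, b or c) marks the same culture at each time. The adjusted p therefore takes the library as its unit. It weighs a difference between times against the spread within times of all 15 libraries. Whether libraries of different times came from separate cultures is not known.

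The submitters' notes name HISAT2 without a version. The read counter, genome build and annotation release are not given in the sources used here. The deposited table gives, per the file headers, an expected count and an FPKM value per gene and library. The deposited counts are estimated counts (expected counts), whole in the table and not scaled to depth. FPKM values were calculated by the authors, scaled by gene length and library depth. For 545 low values with a count between 2 and 5, the value recalculated from FPKM lay in the unit below the count in 90.6% and was whole within a tolerance of 0.05 in 13.6%, so the counts were read as fractional estimates rounded up. The counts were used for all tests, and FPKM only to estimate gene length and to bound background. The reference table held 160 organelle genes, of which 0 matched an ID of the deposited table, so no positions were used.

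Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, TMM scaling, quasi-likelihood F-test over the 15 libraries with 5 group means), limma 3.58.1 and DESeq2 1.42.0 as an alternative. Figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. The filter left 9321 of 10434 genes and removed 1113, of which 336 had 0 counts in all libraries. Each later time was compared with 0 h, successive times were compared with each other, and an F-test took the 4 comparisons with 0 h together. Benjamini-Hochberg adjustment was applied over the tested genes of each comparison at 0.05. Principal components and correlations used log2 CPM with a prior count of 2. Tests were two-sided.

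There were 40 gene lists, matched to the descriptions in the table and written before the data were examined, as were the comparisons, their tests and the rule for named genes. They were tested with limma's camera at a preset correlation of 0.01, adjusted over 39 lists and 4 comparisons (156 tests). The list on galactolipid synthesis had fewer than 3 tested genes and was not tested. Camera was repeated with an estimated correlation, and fry tested whether the genes of a list moved, on balance, one way. Median, mean and camera direction differed in sign for no called list. In all, 1642 genes were in a list and 86 in several. The matching is imperfect, so some lists hold genes that their name does not cover.

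Named genes followed a rule. For each comparison with 0 h it took the 6 largest rises and the 6 largest falls among called genes with a mean log2 CPM of at least 3, a description and 3 libraries all on 1 side of the 3 libraries of 0 h (which chance gives in 10% of 3 against 3 comparisons). It took 3 of each for successive times. For each list it took the 2 members with the largest rise and the 2 with the largest fall. The rule gave 181 genes and 207 results, of which the text gives those that fit its groups.

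Total counts per library were 16649421 to 26349336, and the 10 most abundant genes took 6.3% to 8.6% of them. A count of 0 allows up to 3 counts, or 0.114 to 0.18 CPM, counting error only. No pair of libraries of the same time was a copy, with a chi-square per degree of freedom of 58.1 to 134.5 between them. After removal of the group means, the correlation between libraries with the same letter lay between -0.088 and 0.077, with 0 of 30 pairs above 0.1, and 5 of 15 libraries were closest to their own letter. The letter was therefore not used as a block, except as an alternative.

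The alternatives were DESeq2 size factors or upper-quartile factors in edgeR, DESeq2 itself, no filter on low counts, a filter of at least 50 counts in 3 libraries, the letter as a block, only the 6 libraries compared, a 2-fold threshold, each library left out in turn, and, for the lists, the estimated correlation and fry. Added after the data were seen were runs without the 348 tested genes that lay under 10 counts in 1 library and at 100 or more in another of the same time, camera on successive times, and camera on the functional classes of the table. Splits of the libraries into other groups were also tested.

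The steps were tested on simulated data with the depth and spread of the real libraries. The first bar, recovery of 80% of genes changed 4-fold in every comparison, was missed in 1 of 8 comparisons (77.3%, with 87.9% the highest). Most of the missed genes had a high dispersion, the fitted folds were unbiased and 2% to 5.1% of calls were false. After it was missed, the bar was therefore replaced by a check of bias, false calls and recovery among genes with a dispersion under 0.1 (7515 of 9321). Of the changed genes among these, at least 98% were recovered at 4-fold. Over the 4 comparisons with 0 h, 11.9% to 16.4% of genes changed 1.5-fold and 50.7% to 61.2% of genes changed 2-fold were recovered, so small changes can be missed. Only 66 or 67 genes per fold and time were changed there, while 4285 to 6037 genes were called in the real comparisons with 0 h. The threshold depends on how many genes change, so these shares may differ in the real data. A simulated list of 40 genes raised 1.5-fold was called (adjusted p = 1.7e-40, and adjusted p = 2.8e-06 with an estimated correlation) and 0 of 159 other tests were. The 39 other simulated lists held random genes. In the real lists, the estimated correlation between genes lay between -0.184 (genes of other organisms) and 0.333 (light-harvesting proteins). The 0 calls therefore do not show how often camera with a preset correlation would falsely call lists whose genes vary together.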

Results

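RNA was sequenced from Nannochloropsis oceanica strain IMET1, a unicellular marine microalga that stores oil, at 5 times of phosphate deprivation. The times were 0, 6, 12, 24 and 48 h, with 3 libraries at each (replicates a, b and c), 15 libraries in all. The submitters grew the cells under continuous light, washed them in seawater and moved them to medium without phosphate. Every library, including those of 0 h, is labelled as phosphate deprivation, although the 0 h titles lack the P that the titles of later times carry. The labels also describe cultures moved to complete medium, but none of the 15 libraries is labelled as one, so time since transfer, handling and deprivation cannot be told apart, and 0 h was the only baseline. The table held 10434 genes, 10316 of them annotated and 118 newly assembled, and 9321 had enough counts to be tested. Total counts at 0 h were 18013512, 21231074 and 24955189 for replicates a, b and c. In the same order, they were 16661053, 16695564 and 26349336 at 6 h, 21655636, 17672754 and 16649421 at 12 h, 22287807, 18135488 and 22161736 at 24 h, and 17674092, 20576407 and 19368532 at 48 h. The most abundant transcript, NO25G00860, took 2.35% to 3.47% of the counts of a library. Gene names are the homology annotations of the table and do not show function in this species. Levels are given as the mean ± SD in CPM (counts relative to the scaled library total) of the 3 libraries of a time, and differences as log2 fold changes ± SE with n = 3 per time. The SE is the absolute log2 fold change divided by the square root of the F statistic of the edgeR fit of all 15 libraries. It therefore does not measure the spread of the compared libraries alone. Chromosomal positions and the genome build are not given in the sources used here.

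The libraries of a time resembled each other more than those of other times. The correlation of log2 CPM across genes, which are not independent replicates, lay between 0.908 and 0.93 within times and between 0.771 and 0.806 for 0 h against 12 h, the lowest pair of times. For 24 h against 48 h it lay between 0.893 and 0.914, which overlaps the range within times. On the first principal component, with 28.1% of the variance, the 0 h libraries lay between -68.9 and -63.6 and the 12 h libraries between 64.0 and 73.2. The second component, with 12.8%, set the 48 h libraries (-51.9 to -37.3) against those of 6 h (38.9 to 44.1).

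**Figure D1:**
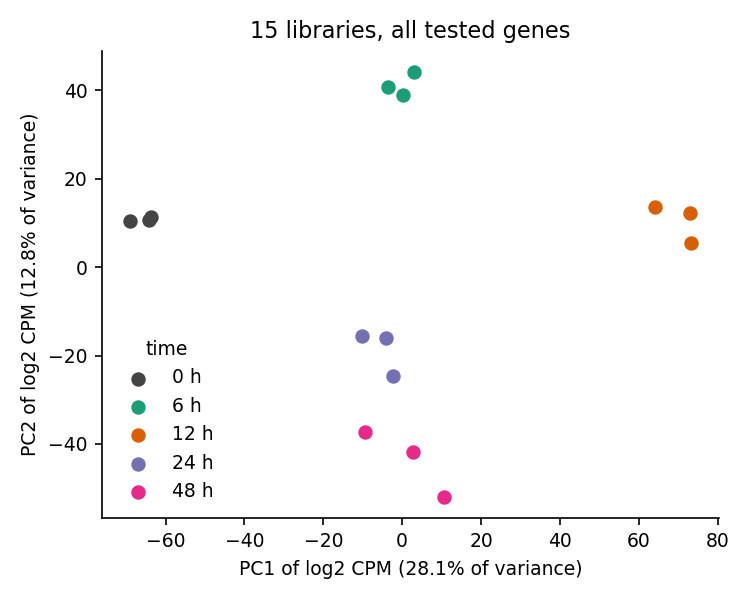
Principal components 1 and 2 of the log2 CPM of the tested genes, in arbitrary units, with 1 point per library and 1 colour per time. The 3 libraries of 0 h and of 12 h lie at opposite ends of the first component, between -68.9 and -63.6 and between 64.0 and 73.2.

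The comparison of 6 h with 0 h asked which transcripts changed early after transfer to medium without phosphate. Transcripts of cell division and DNA synthesis rose. Cyclin-A1-1 (NO13G01690), a regulator of cell cycle transitions, rose from 0.929 ± 0.245 to 61.9 ± 15.4 CPM, a log2 fold change of 6.05 ± 0.28 (edgeR adjusted p = 2.9e-08). The mitotic kinase Nek2 (NO17G02980) rose from 1.73 ± 0.107 to 72.1 ± 18.9 CPM (log2 fold change 5.38 ± 0.20). The microtubule subunit tubulin beta-5 (NO04G01220) rose from 7.80 ± 0.240 to 151.2 ± 28.7 CPM (log2 fold change 4.27 ± 0.16, edgeR adjusted p = 6.9e-09, as for Nek2). The ribonucleotide reductase small chain (NO04G04660), which makes DNA precursors, rose from 8.49 ± 0.516 to 150.1 ± 48.3 CPM, by 4.14 ± 0.22 (edgeR adjusted p = 6.3e-08). Of the 179 tested genes of DNA replication and the cell cycle, 93 rose and 23 fell (94 and 24 adjusted over the list alone), with a median log2 fold change of 0.62. The list was called up by camera (adjusted p = 2.5e-06, and adjusted p = 0.24 with an estimated correlation).

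Transcripts of the protein synthesis machinery moved apart at 6 h. Of 99 tested genes for cytosolic ribosomal proteins, 69 rose and 10 fell (69 and 11 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 2.5e-11, and adjusted p = 0.31 with an estimated correlation). The 40S protein S29 (newGene_40) stood at 84.2 ± 4.99 CPM at 0 h and rose to its highest level, 279.5 ± 38.8 CPM, at 12 h. Of 95 genes of ribosome biogenesis and rRNA processing, 4 rose and 46 fell (4 and 49 adjusted over the list alone; camera adjusted p = 4.7e-05, and adjusted p = 0.24 with an estimated correlation). This list also took in a histone H1 gene (NO03G01950), which packs DNA and was one of the 4 risers. Of 27 genes for organellar ribosomal proteins, 1 rose and 11 fell (1 and 11 adjusted over the list alone; camera adjusted p = 0.028, and adjusted p = 0.33 with an estimated correlation). Among the fallers was the chloroplast protein S1 (NO06G01110), with a log2 fold change of -1.02 ± 0.23 (edgeR adjusted p = 0.0027). Of 157 genes of the proteasome and ubiquitin conjugation, 56 rose and 31 fell (56 and 31 adjusted over the list alone; camera adjusted p = 0.033, and adjusted p = 0.27 with an estimated correlation).

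Transcripts of photosynthesis, carbon fixation and glycolysis were lower at 6 h. Of 18 genes of the photosystems and electron transport, 14 fell and 0 rose (14 and 0 adjusted over the list alone). Of 25 genes for light-harvesting proteins, 20 fell and 1 rose (21 and 1 adjusted over the list alone). The riser was a fucoxanthin-chlorophyll a-c binding protein (NO18G00330), which went from 134.6 ± 1.88 to 605.8 ± 37.3 CPM (log2 fold change 2.17 ± 0.07, edgeR adjusted p = 2.6e-09). Among 25 chlorophyll and porphyrin genes 17 fell and 3 rose (17 and 3 adjusted over the list alone). Among 26 carotenoid genes 15 fell and 0 rose (16 and 0 adjusted over the list alone), and among 26 genes of carbon fixation 16 fell and 3 rose (16 and 3 adjusted over the list alone). Camera called these 5 lists down, with adjusted p = 4.1e-05, 8.7e-05, 2.3e-05, 0.00095 and 0.00074 in that order, and adjusted p = 0.24, 0.34, 0.27, 0.27 and 0.24 with an estimated correlation. Glycolysis and gluconeogenesis (3 of 46 rose and 23 fell; 4 and 23 adjusted over the list alone) was called down at adjusted p = 0.01, and adjusted p = 0.24 with an estimated correlation. The tricarboxylic acid cycle (12 of 23 rose and 1 fell; 13 and 1 adjusted over the list alone) was called up at adjusted p = 0.033, and adjusted p = 0.34 with an estimated correlation. The respiratory chain (1 of 46 rose and 17 fell; 1 and 16 adjusted over the list alone) was called down at adjusted p = 0.033, and adjusted p = 0.37 with an estimated correlation. Its call ended without 0 h replicate c (camera adjusted p = 0.051). Nitrogen uptake and assimilation (4 of 29 rose and 14 fell; 4 and 14 adjusted over the list alone) was called down at adjusted p = 0.037, and adjusted p = 0.33 with an estimated correlation. Its call ended without 6 h replicate c (camera adjusted p = 0.056).

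Over all genes, 2298 were higher and 2394 lower at 6 h than at 0 h by the edgeR test, of which 937 and 430 changed at least 2-fold. With DESeq2 size factors 2430 were higher and 2262 lower, and with upper-quartile scaling 2374 and 2288, so which direction was more frequent depends on the scaling. A phosphate transporter, annotated as transporter 1-12 (NO16G01940), fell from 1503 ± 69.3 to 509.5 ± 30.2 CPM (log2 fold change -1.56 ± 0.08, edgeR adjusted p = 3.6e-08). The chloroplast peptidyl-prolyl isomerase CYP38 (NO03G03320) rose by 4.96 ± 0.63, and by 6.28 without 0 h replicate a. Other large falls were those of RNA pseudouridine synthase 6 (NO20G01690), with a log2 fold change of -2.46 ± 0.23, and of T-complex 11 (NO03G01840), from 574.8 ± 41.3 to 46.0 ± 5.56 CPM. The clock-type transcription factor CCA1 (NO01G04790) fell from 873.8 ± 486 to 195.4 ± 48.3 CPM. The NADH-ubiquinone reductase MLRQ subunit (NO09G00200) stood at 41.3 ± 35.6 CPM at 0 h, with libraries far apart, and at 0.194 ± 0.0475 CPM at 6 h.

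The comparison of 12 h with 0 h had the most genes called of the 4 comparisons with 0 h. Genes annotated for lipid metabolism were among those with large changes. Phospholipase D zeta 2 (NO06G04260), which cleaves phospholipids, rose from 11.4 ± 0.694 to 154.0 ± 3.46 CPM, a log2 fold change of 3.75 ± 0.23 (edgeR adjusted p = 3.2e-08). A sulfoquinovosyl transferase SQD2 (NO01G02630), the last enzyme of synthesis of a lipid without phosphorus, rose from 26 ± 2.46 to 219.0 ± 31.9 CPM, by 3.08 ± 0.25 (edgeR adjusted p = 4.3e-07). The lipid droplet surface protein (NO11G02550) rose from 208.8 ± 1.92 to 1595 ± 52.1 CPM, by 2.93 ± 0.09 (edgeR adjusted p = 6.3e-10). Diacylglycerol O-acyltransferase 2 (NO19G01680), which makes triacylglycerol, fell from 232.4 ± 1.69 to 92.1 ± 2.77 CPM, with a log2 fold change of -1.34 ± 0.13 (edgeR adjusted p = 2.3e-06).

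The lists on lipids held members that moved both ways at 12 h, and none of them was called by camera. Of 29 genes of phospholipid breakdown, 13 rose and 8 fell (13 and 8 adjusted over the list alone). Of 17 genes of phospholipid synthesis, 3 rose and 8 fell (3 and 8 adjusted over the list alone), and of 7 of betaine lipid and sulfolipid synthesis, 3 rose and 1 fell (3 and 1 adjusted over the list alone). The faller, betaine lipid synthase (NO05G01490), went from 128.8 ± 12.6 to 59.2 ± 1.12 CPM. Of 34 genes of triacylglycerol synthesis and the lipid droplet, 5 rose and 12 fell (5 and 12 adjusted over the list alone), and of 24 lipases 13 rose and 4 fell (13 and 5 adjusted over the list alone). Among 26 genes of fatty acid synthesis 6 rose and 14 fell (6 and 14 adjusted over the list alone). Acetyl-CoA carboxylase 2 (NO09G00220), which catalyses the committed step, fell from 5313 ± 211 to 1309 ± 90.7 CPM (log2 fold change -2.02 ± 0.08, edgeR adjusted p = 1.8e-09). A mitochondrial 3-oxoacyl synthase (NO03G02790) rose from 178.4 ± 15.4 to 884.8 ± 130 CPM. Of 34 genes of fatty acid desaturation and elongation, 10 rose and 12 fell (10 and 12 adjusted over the list alone), and of 36 of beta-oxidation, 12 rose and 13 fell (12 and 13 adjusted over the list alone). Peroxisomal acyl-CoA synthetase 7 (NO25G00730), of the last list, fell from 342.9 ± 115 to 4.95 ± 2.26 CPM, and peroxisomal 3-ketoacyl-CoA thiolase 2 (NO25G01710) rose from 70 ± 1.18 to 269.0 ± 16.1 CPM.

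Among transcripts linked to phosphate at 12 h, an SPX domain membrane protein (NO04G02810), from a family that senses phosphate status, rose from 36.0 ± 1.61 to 193.6 ± 27.6 CPM (log2 fold change 2.43 ± 0.24, edgeR adjusted p = 2.0e-06). Of the 18 tested genes of phosphate transport and SPX proteins, 6 rose and 4 fell (6 and 4 adjusted over the list alone), with a median of 0.05 that became -0.01 under upper-quartile scaling, and camera made no call. Of 16 phosphatases, 6 rose and 6 fell (6 and 6 adjusted over the list alone). Of 7 genes of the polyphosphate list, 4 rose and 0 fell (4 and 0 adjusted over the list alone). A membrane pyrophosphatase (NO19G01860), a proton pump that splits pyrophosphate, rose from 60 ± 0.505 to 291.4 ± 13.1 CPM (log2 fold change 2.28 ± 0.11, edgeR adjusted p = 7.8e-09). The sulfate transporter 3.5 (NO17G02590) rose from 54.9 ± 4.78 to 560.5 ± 6.37 CPM, by 3.35 ± 0.17 (edgeR adjusted p = 8.6e-09). ATP sulfurylase 2 (NO14G02380), which activates sulfate, fell from 359.7 ± 7.51 to 99.0 ± 8.67 CPM. The sulfur list had 10 of 31 genes up and 10 down (10 and 10 adjusted over the list alone).

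Transcripts of photosynthesis were lower at 12 h as well. The magnesium chelatase subunit ChlH (NO22G01810), which starts chlorophyll synthesis, fell from 3641 ± 125 to 892.5 ± 137 CPM (log2 fold change -2.03 ± 0.11, edgeR adjusted p = 1.2e-08). Sedoheptulose-1,7-bisphosphatase of the Calvin cycle (NO11G01900) fell from 2247 ± 13.0 to 391.1 ± 18.1 CPM (-2.52 ± 0.09, edgeR adjusted p = 1.0e-09). Alpha carbonic anhydrase 4 (NO20G00630) fell from 1479 ± 27.6 to 199.8 ± 16.2 CPM (-2.89 ± 0.11), and lycopene beta cyclase (NO10G02110) from 305.6 ± 8.22 to 61.5 ± 2.75 CPM (-2.31 ± 0.06). Of the light-harvesting genes 19 fell and 1 rose (19 and 1 adjusted over the list alone), and of the photosystem genes 14 fell and 0 rose (14 and 0 adjusted over the list alone). In the chlorophyll list 18 fell and 3 rose (18 and 3 adjusted over the list alone), and in the carotenoid list 16 fell and 4 rose (16 and 4 adjusted over the list alone). In carbon fixation 16 fell and 3 rose (16 and 3 adjusted over the list alone). Camera called these 5 lists down at 12 h with adjusted p = 0.00023, 0.00028, 8.7e-05, 0.0049 and 0.0055, and adjusted p = 0.35, 0.24, 0.27, 0.27 and 0.27 with an estimated correlation. Glycolysis (27 fell, 7 rose; 27 and 7 adjusted over the list alone) was called down at adjusted p = 0.009, and adjusted p = 0.24 with an estimated correlation. Nitrogen assimilation (12 fell, 2 rose; 12 and 2 adjusted over the list alone) was called down at adjusted p = 0.037, and adjusted p = 0.33 with an estimated correlation. Its call ended without 0 h replicate a (camera adjusted p = 0.052) or 6 h replicate a (camera adjusted p = 0.051).

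Other lists rose at 12 h. Of 12 histone genes 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.35 with an estimated correlation). A histone H2A variant (NO22G01340) rose from 165.6 ± 3.13 to 1619 ± 250 CPM (3.29 ± 0.18, edgeR adjusted p = 1.8e-08). The cytosolic ribosomal proteins (72 rose, 8 fell; 73 and 9 adjusted over the list alone) had a median of 1.11 (camera adjusted p = 2.1e-09, and adjusted p = 0.34 with an estimated correlation). DNA replication and cell cycle (94 rose, 31 fell; 95 and 32 adjusted over the list alone) was called at adjusted p = 0.00095, and adjusted p = 0.27 with an estimated correlation. The tricarboxylic acid cycle (15 rose, 3 fell; 15 and 3 adjusted over the list alone) was called at adjusted p = 0.0055, and adjusted p = 0.30 with an estimated correlation. Its member 2-oxoglutarate dehydrogenase E1 (NO16G00280) rose from 29.9 ± 2.15 to 138.5 ± 2.86 CPM. The heat shock proteins and chaperones (39 of 104 rose and 31 fell; 39 and 31 adjusted over the list alone) were not called by camera at 12 h (adjusted p = 0.28). Their member endoplasmin (NO09G02640), a chaperone of the endoplasmic reticulum, rose from 229.6 ± 9.94 to 2741 ± 125 CPM (3.58 ± 0.15, edgeR adjusted p = 3.3e-09). Heat stress transcription factor B-2a (NO14G01060) rose from 7.60 ± 0.114 to 193.1 ± 11.8 CPM (4.67 ± 0.21, edgeR adjusted p = 4.0e-09). A plasma membrane proton ATPase (NO12G00370) fell from 8610 ± 171 to 1578 ± 233 CPM.

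Over all genes, 2990 were higher and 3047 lower at 12 h than at 0 h, of which 1787 and 961 changed at least 2-fold. Upper-quartile scaling moved the median log2 fold change of all tested genes from -0.04 to -0.104, with 2819 genes higher and 3261 lower, and DESeq2 size factors gave 3044 and 2973. Changes near 0 and the balance of directions at 12 h therefore depend on the scaling. Among the largest fitted falls, cytosolic fructose-bisphosphate aldolase 8 (NO01G03170) stood at 424.9 ± 368 CPM at 0 h and 0.0764 ± 0.0424 CPM at 12 h. A PDZ domain protein (NO10G02750) stood at 41.3 ± 1.13 and 0.442 ± 0.110 CPM. Both belong to the 348 tested genes whose libraries of a single time differed between fewer than 10 and at least 100 counts.

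**Figure D2:**
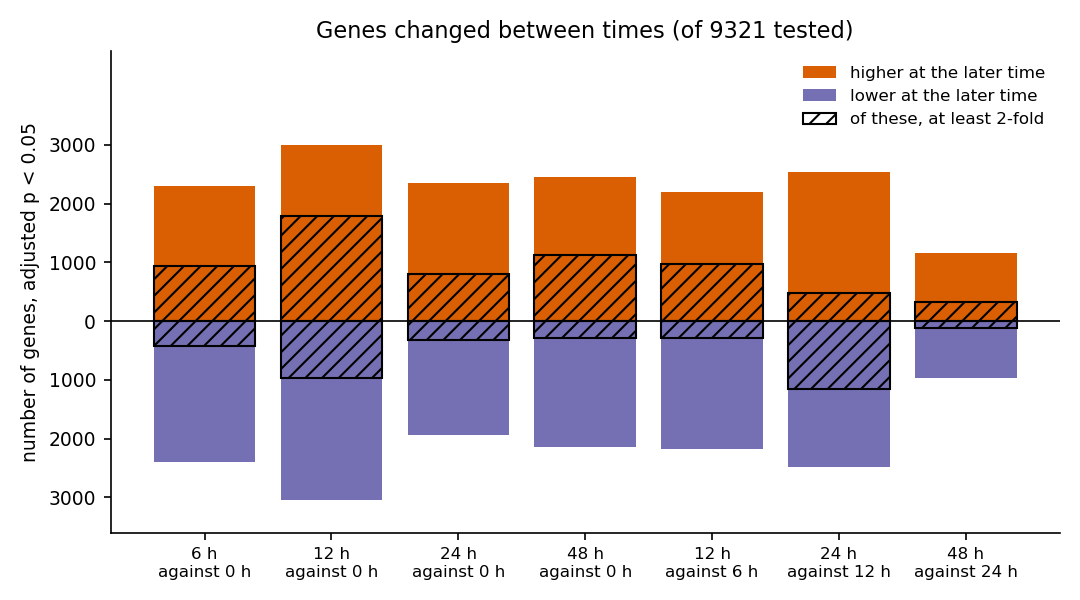
Number of genes called by edgeR at an adjusted p under 0.05 in each comparison, out of 9321 tested, with genes higher at the later time above the line and lower ones under it, and those changed at least 2-fold hatched. The bars reach from 969 genes lower at 48 h than at 24 h to 3047 lower at 12 h than at 0 h.

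At 24 h transcripts of cytosolic ribosomal proteins were higher than at 0 h. Of the 99 genes, 72 rose and 7 fell (73 and 7 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 4.0e-13, and adjusted p = 0.30 with an estimated correlation). Cyclin-A1-1 (NO13G01690) stood at 16 ± 2.93 CPM, above 0 h by a log2 fold change of 4.10 ± 0.26 (edgeR adjusted p = 3.8e-07), and Nek2 (NO17G02980) at 24.2 ± 3.39 CPM, above by 3.81 ± 0.19. Of the cell cycle genes, 66 rose and 19 fell (66 and 20 adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.34 with an estimated correlation). Of 36 genes of nucleotide synthesis 18 rose and 2 fell (18 and 3 adjusted over the list alone; camera adjusted p = 0.0026, and adjusted p = 0.30 with an estimated correlation). Of the tricarboxylic acid cycle genes 13 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 0.0042, and adjusted p = 0.27 with an estimated correlation). A plasma membrane proton ATPase (NO17G00440) rose from 513.6 ± 11.1 to 1336 ± 128 CPM (1.38 ± 0.09, edgeR adjusted p = 4.8e-07).

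The lists of photosynthesis were called down at 24 h as well. In light harvesting 16 genes fell and 1 rose (17 and 1 adjusted over the list alone), and in the photosystems 11 fell and 0 rose (12 and 1 adjusted over the list alone). In chlorophyll synthesis 12 fell and 3 rose (12 and 3 adjusted over the list alone), and in carotenoid synthesis 12 fell and 2 rose (12 and 2 adjusted over the list alone). In carbon fixation 12 fell and 5 rose (12 and 5 adjusted over the list alone). In that order, camera gave adjusted p = 0.0003, 0.008, 0.0086, 0.0042 and 0.033, and adjusted p = 0.35, 0.27, 0.34, 0.27 and 0.30 with an estimated correlation. Sphingolipid and sterol synthesis (6 of 45 rose, 15 fell; 6 and 15 adjusted over the list alone) was called down at adjusted p = 0.031, and adjusted p = 0.27 with an estimated correlation. Its call ended without 24 h replicate a (camera adjusted p = 0.054). Its member sphingosine-1-phosphate lyase (NO05G04550) was lowest at 12 h, with 168.9 ± 1.83 CPM at 0 h and 29.4 ± 5.20 CPM at 12 h.

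Over all genes, 2349 were higher and 1936 lower at 24 h than at 0 h, of which 798 and 314 changed at least 2-fold. Among the largest falls, a zinc metalloendopeptidase (NO27G01580) went from 58.8 ± 4.47 to 1.65 ± 0.176 CPM (-5.15 ± 0.18, edgeR adjusted p = 1.5e-08). The blue light receptor phototropin-1B (NO01G04880) went from 235.6 ± 16.4 to 26 ± 8.06 CPM (-3.18 ± 0.31, edgeR adjusted p = 6.6e-06). Among the rises, cation/proton antiporter 18 (NO25G02020) went from 1.39 ± 0.501 to 38.5 ± 45.4 CPM (4.78 ± 1.31), and by 3.15 without 24 h replicate a. The rise of serine carboxypeptidase-like 48 (NO03G05650), by 3.65 ± 1.19, was 0.53 without 24 h replicate c, with an edgeR adjusted p = 0.59.

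At 48 h, genes annotated for phosphate uptake, sulfolipid synthesis and phospholipid cleavage were among those higher than at 0 h. Phosphate transporter 1-4 (NO03G01310) rose from 80.2 ± 1.82 to 409.4 ± 12.4 CPM, a log2 fold change of 2.35 ± 0.18 (edgeR adjusted p = 1.5e-06). Another SQD2 gene (NO15G02830) rose from 5.83 ± 0.753 to 129.6 ± 19.4 CPM, by 4.47 ± 0.42 (edgeR adjusted p = 4.9e-06). A secretory phospholipase A2 (NO04G01800), which cleaves phospholipids, rose from 4.70 ± 0.339 to 81.9 ± 10.7 CPM, by 4.12 ± 0.18 (edgeR adjusted p = 3.8e-08). An alkaline phosphatase-like gene (NO16G02990), from a family that frees phosphate from organic compounds, rose from 5.62 ± 0.371 to 45.3 ± 18.8 CPM, by 3.01 ± 0.29 (edgeR adjusted p = 5.7e-06). These genes were picked as large risers, and their lists moved both ways. Of 16 phosphatases, 5 rose and 5 fell, with a median of 0. Of 29 genes of phospholipid breakdown, 10 rose and 5 fell (camera adjusted p = 0.39). Of 7 genes of betaine lipid and sulfolipid synthesis, 3 rose and 2 fell (camera adjusted p = 0.88). Camera called none of these lists at 48 h. Of the 18 genes of phosphate transport and SPX proteins, 11 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 0.036, and adjusted p = 0.27 with an estimated correlation). The fallers were an ADP,ATP carrier (NO08G02900), from a family that exchanges nucleotides across membranes, and anion transporter 4 (NO08G00240). The risers included an ascorbate transporter (NO07G04660) and a mitochondrial thiamine diphosphate carrier (NO24G00760), which are named for other substrates. Whether they also carry phosphate is not known from these data. These last 3 genes were chosen after their values were seen.

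**Figure D3:**
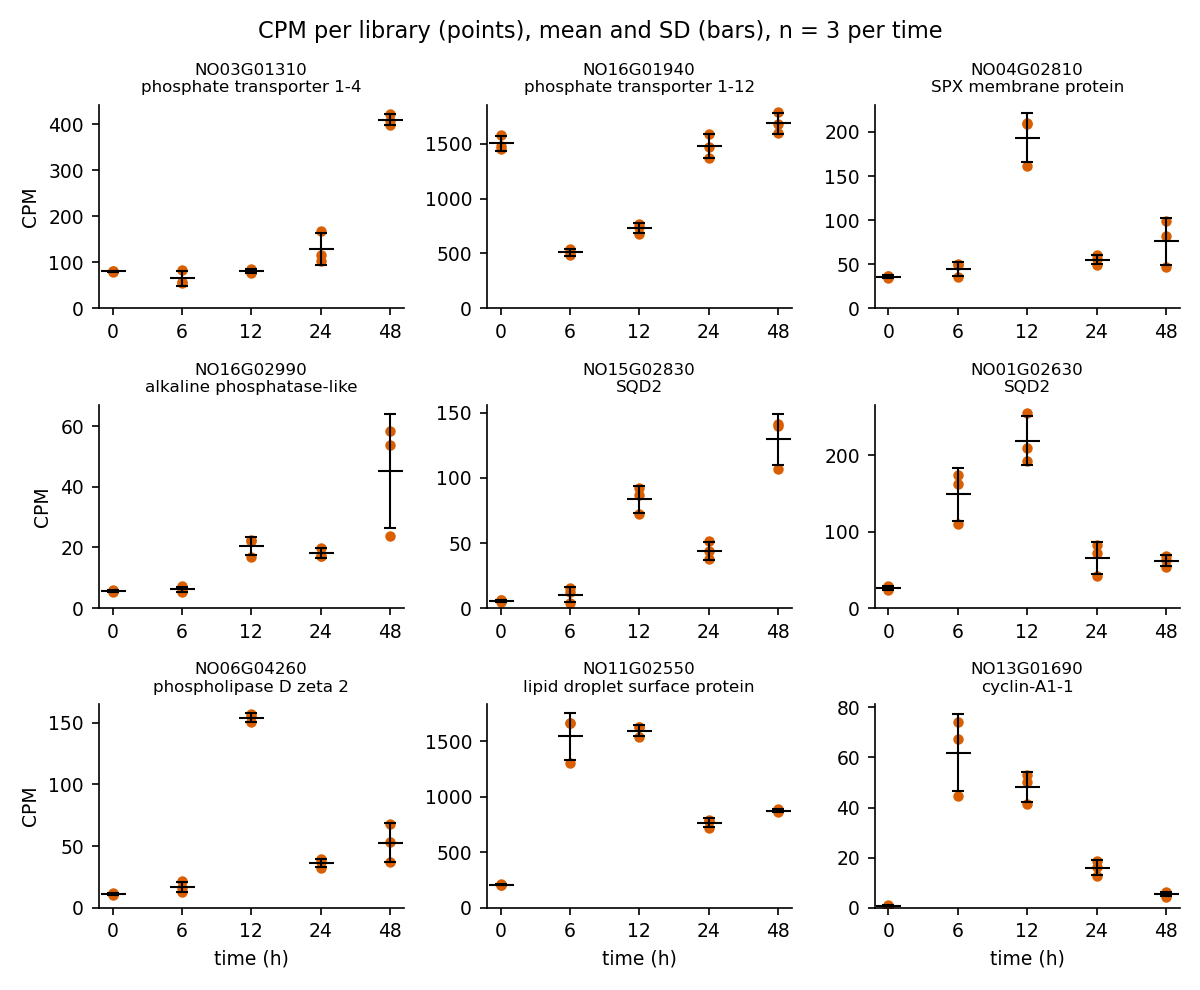
Level in CPM of 9 named genes, each with its own axis from 0, against time in hours (times evenly spaced, not to scale), with 1 point per library and black bars for the mean and SD of the 3 libraries. Phosphate transporter 1-4 (NO03G01310) lies at a mean of 80.2 CPM at 0 h and 409.4 CPM at 48 h, and phosphate transporter 1-12 (NO16G01940) at 1503 CPM at 0 h and 509.5 CPM at 6 h.

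The delta-12 desaturases NO11G02480 and NO14G02790, which add a double bond to oleic acid, fell at 48 h from 408.7 ± 9.37 to 47.7 ± 10.9 CPM (-3.10 ± 0.39, edgeR adjusted p = 4.6e-05) and from 422.0 ± 7.14 to 66.9 ± 29.5 CPM (-2.66 ± 0.41, edgeR adjusted p = 0.0002). These genes share a description, so reads could not be shown to belong to only 1 of them. Nitrate reductase (NO09G02340) rose from 150.3 ± 3.09 to 565.2 ± 29.4 CPM (1.91 ± 0.12, edgeR adjusted p = 3.9e-07). Ferredoxin-nitrite reductase (NO26G00710), the next enzyme of nitrate use, fell from 3624 ± 142 to 1377 ± 52.7 CPM (-1.40 ± 0.12, edgeR adjusted p = 3.2e-06). A cytochrome b6-f iron-sulfur subunit (NO05G02070) rose from 221.5 ± 45.1 to 623.1 ± 85.7 CPM (1.49 ± 0.16), and monodehydroascorbate reductase 4 (NO28G01700), an antioxidant enzyme, from 64.4 ± 1.03 to 324.8 ± 38.4 CPM (2.34 ± 0.12).

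Of 104 genes for heat shock proteins and chaperones, 43 rose and 14 fell at 48 h (43 and 14 adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.24 with an estimated correlation). The tricarboxylic acid cycle (17 rose, 2 fell; 17 and 2 adjusted over the list alone) was called up at adjusted p = 0.00074, and adjusted p = 0.27 with an estimated correlation. In light harvesting 19 genes fell and 2 rose (20 and 2 adjusted over the list alone), and in the photosystems 13 fell and 2 rose (13 and 2 adjusted over the list alone). In chlorophyll synthesis 16 fell and 4 rose (17 and 4 adjusted over the list alone), and in carotenoid synthesis 13 fell and 3 rose (13 and 3 adjusted over the list alone). In carbon fixation 14 fell and 2 rose (14 and 2 adjusted over the list alone). Camera called these 5 lists down at 48 h with adjusted p = 5.3e-05, 0.0023, 0.00028, 0.0055 and 0.0066, and adjusted p = 0.34, 0.27, 0.27, 0.27 and 0.27 with an estimated correlation. Organellar ribosomal proteins (15 fell, 2 rose; 15 and 2 adjusted over the list alone) were called down at adjusted p = 0.0047, and adjusted p = 0.27 with an estimated correlation. Cytosolic ribosomal proteins (28 fell, 3 rose; 28 and 3 adjusted over the list alone) had a median of -0.14 and were called down at adjusted p = 0.011, and adjusted p = 0.65 with an estimated correlation. This call ended without 48 h replicate b (camera adjusted p = 0.061). The cell cycle list (65 rose, 23 fell; 65 and 23 adjusted over the list alone) missed the threshold (adjusted p = 0.071).

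Over all genes, 2454 were higher and 2143 lower at 48 h than at 0 h, of which 1121 and 283 changed at least 2-fold. T-complex 11 (NO03G01840) stood at a mean of 4.30 CPM, with a log2 fold change of -7.06 ± 0.55 (edgeR adjusted p = 1.5e-06). Antiporter 18 (NO25G02020) stood at 59.3 ± 3.56 CPM, higher by 5.40 ± 1.35 (edgeR adjusted p = 0.0055). Of the 39 lists tested, camera called 14, 11, 10 and 11 at 6, 12, 24 and 48 h, 46 of 156 tests, and with an estimated correlation 0 of 156.

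**Figure D4:**
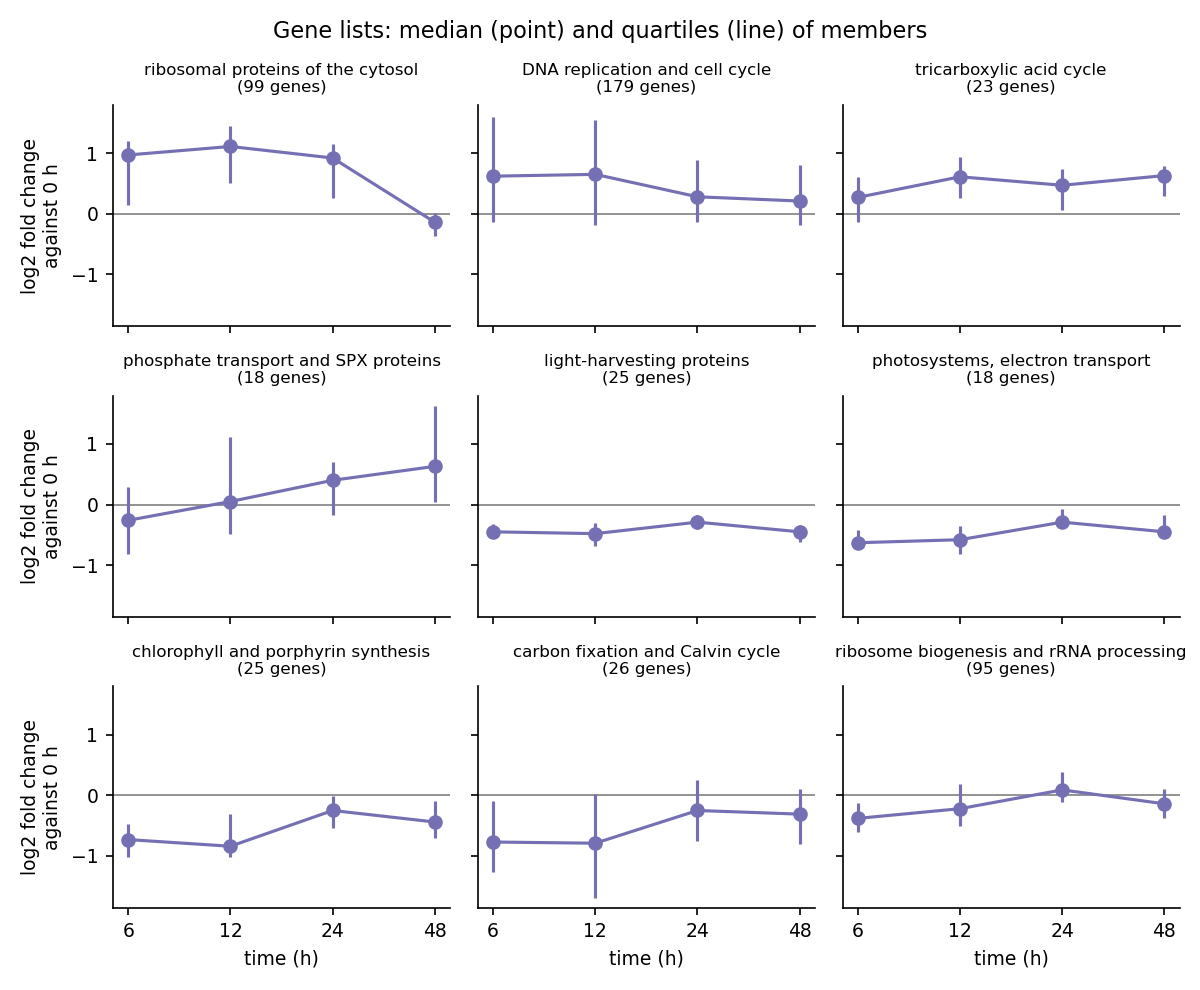
Log2 fold change against 0 h of 9 gene lists at 6, 12, 24 and 48 h (times evenly spaced, not to scale), with points for the median and vertical lines for the quartiles of the tested members, not errors between libraries. The medians of the cytosolic ribosomal proteins lie at 0.97, 1.11, 0.92 and -0.14, and that of the phosphate list at 12 h, 0.05, became -0.01 under upper-quartile scaling.

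Successive times were compared to date the changes. Between 6 and 12 h, the GDP-fucose transporter 1 (NO08G01610), a carrier of sugar nucleotides, rose from 2.68 ± 0.380 to 39.9 ± 0.765 CPM (3.89 ± 0.45, edgeR adjusted p = 2.6e-05). A pentatricopeptide repeat protein (NO26G01440) rose from 50.4 ± 13.7 to 928.2 ± 51.6 CPM (4.20 ± 0.71, edgeR adjusted p = 0.00043), and a phosphoesterase (NO11G03580) fell from 223.1 ± 19.0 to 11.2 ± 4.83 CPM (-4.32 ± 0.93, edgeR adjusted p = 0.0023). Of the tested genes 2190 were higher and 2168 lower at 12 h than at 6 h (1901 and 2612 under upper-quartile scaling), and 970 and 290 changed at least 2-fold. Between 12 and 24 h, cell cycle transcripts fell in 82 genes and rose in 20 (82 and 20 adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.22 with an estimated correlation). Histone transcripts fell in 10 of 12 and rose in 0 (10 and 0 adjusted over the list alone; adjusted p = 0.0058, and adjusted p = 0.34 with an estimated correlation). Carbon fixation rose in 17 and fell in 2 (18 and 2 adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.15 with an estimated correlation). Chlorophyll synthesis rose in 19 and fell in 3 (19 and 3 adjusted over the list alone; adjusted p = 5.4e-05, and adjusted p = 0.22 with an estimated correlation). Over all genes 2535 were higher and 2475 lower at 24 h than at 12 h, of which 473 and 1149 changed at least 2-fold. With upper-quartile scaling 2896 were higher and 2176 lower, and with DESeq2 size factors 2460 and 2541, so the balance of directions here and between 6 and 12 h depends on the scaling. CMP-sialic acid transporter 2 (NO22G01080) fell from 60.4 ± 15.5 to 5.01 ± 0.529 CPM (-3.59 ± 0.34, edgeR adjusted p = 3.6e-06). A glycoside hydrolase of family 8 (NO12G02250) rose from 6.20 ± 0.392 to 146.3 ± 4.05 CPM (4.56 ± 1.08, edgeR adjusted p = 0.0036). Camera on successive times was added after the data were seen.

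Between 24 and 48 h, transcripts of ribosomes fell. Of the cytosolic ribosomal protein genes, 75 fell and 1 rose (77 and 1 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 3.5e-41, and adjusted p = 0.093 with an estimated correlation). Of the ribosome biogenesis genes 28 fell and 1 rose (34 and 3 adjusted over the list alone; camera adjusted p = 2.4e-07, and adjusted p = 0.048 with an estimated correlation). Actin (NO03G02590), the subunit of microfilaments, fell from 593.0 ± 34.4 to 63.7 ± 3.70 CPM (-3.22 ± 0.18, edgeR adjusted p = 6.1e-07). The E3 ubiquitin ligase XB3 (NO13G00830) fell from 106.4 ± 22.2 to 18.6 ± 2.32 CPM (-2.51 ± 0.14, edgeR adjusted p = 6.3e-07). The nuclear migration protein NUM1 (NO17G02380) rose from 6.13 ± 0.171 to 52.9 ± 5.30 CPM (3.11 ± 0.19, edgeR adjusted p = 1.2e-06). Over all genes 1151 were higher and 969 lower at 48 h than at 24 h, of which 323 and 116 changed at least 2-fold.

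Over the whole time course, 7083 of 9321 genes changed at any time in the edgeR test over the 4 comparisons with 0 h together. The lipid droplet surface protein (NO11G02550) and fucoxanthin-chlorophyll a-c binding protein (NO18G00330) were higher at each later time. The largest change from 0 h fell at 12 h for 3910 of these genes (55.2%), at 6 h for 1393 (19.7%), at 48 h for 990 (14.0%) and at 24 h for 790 (11.2%). There were 1124 genes higher and 1066 lower at all 4 later times, where independent calls would give 48.9 and 37.4. The 4 comparisons share the 0 h libraries, and in 20 simulations without any change the highest number called at all 4 times was 0, while 39.9% of genes had the same sign at all 4 times, against 58.3% observed. The mean correlation between the fold changes of 2 comparisons was 0.5 in these simulations and 0.66 observed, and the mean covariance 0.17 and 0.96. The simulations hold no effects and the 3 libraries of 0 h could not be divided between the comparisons, so part of the excess over independent calls may come from sharing them. The calls of 733 genes were higher at 1 time and lower at another, among them actin (NO03G02590), which rose at 12 h by 2.18 and was below 0 h at 48 h (-2.57).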

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

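Camera on successive times, the test of scaling and the comparisons with 0 h of single genes without a replicate were chosen after the result was seen; the other tests of this part were chosen before. Each result here was called in opposite directions against 0 h at different times, for genes by at least 2-fold each way. Each also differed between successive times by the test of that difference itself. That test is given for whichever of the 3 successive comparisons had the lowest adjusted p, which was not corrected for this choice.

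The cytosolic ribosomal proteins had medians of 0.97, 1.11 and 0.92 at 6, 12 and 24 h and of -0.14 at 48 h (camera adjusted p = 0.011, and adjusted p = 0.65 with an estimated correlation; the call ended without 48 h replicate b, camera adjusted p = 0.061), and the difference between 48 and 24 h was -1.02 (camera adjusted p = 3.5e-41, and adjusted p = 0.093 with an estimated correlation). Ribosomal protein transcripts are short (median effective length 1341, against 2474 for all tested genes), so a length bias could raise them. In 343 other genes matched in length (median 1560) and level, the medians were -0.18, -0.21 and -0.06, with upper bounds of the 95% bootstrap interval of -0.14, -0.08 and 0.04, which argues against length as the cause of the rise. Over all pairs of a library of 6, 12 or 24 h and one of 0 h, the list's median log2 ratio of unscaled counts was above that of all tested genes by at least 0.8. Between libraries of the same time the difference was at most 0.27. Since 1 factor per library moves all genes alike, it leaves this difference unchanged. The values argue against scaling for the rise relative to all tested genes only, and whether absolute levels rose was not tested. A response to phosphate deprivation, to transfer or to time since transfer remains a hypothesis, and these cannot be separated without the replete cultures, which are not analysed here.

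Actin (NO03G02590) was above 0 h at 12 h by 2.18 and below it at 48 h, and between 24 and 48 h its log2 fold change was -3.22 (edgeR adjusted p = 6.1e-07). The armadillo repeat protein NO29G00310 was below 0 h at 6 h (-2.40) and above it at 24 h (1.71), with a difference of 2.64 between 24 and 12 h (edgeR adjusted p = 0.00014). The GDP-fucose transporter NO08G01610 was below 0 h at 6 h (-1.13) and above it at 12 h (2.76), with a difference of 3.89 (edgeR adjusted p = 2.6e-05). Without 0 h replicate a the log2 fold change of NO08G01610 at 6 h was -0.39 and its call ended (edgeR adjusted p = 0.31), as it did without any single 6 h replicate, while its rise at 12 h was 3.5 without 0 h replicate a. The heat shock protein NO20G02130 was below 0 h at 12 h (-2.38) and above it at 48 h (3.61), with a difference of 4.43 between 48 and 24 h (edgeR adjusted p = 0.0046). Without 0 h replicate a its rise at 48 h was 4.71, while its log2 fold change at 12 h was -1.29 and that call ended (edgeR adjusted p = 0.18), as it did without any single 12 h replicate. The coproporphyrinogen oxidase NO06G04430, of chlorophyll and haem synthesis, was below 0 h at 6 h (-1.14). It was above 0 h at 12 h (0.57), 24 h (1.08) and 48 h (1.20). Its difference between 12 and 6 h was 1.71 (edgeR adjusted p = 2.1e-06).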

How the results depend on the processing

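The count of genes called stayed within 1.5 times its reported value under the other scalings, DESeq2, the filters, the letter block, the fit of 6 libraries alone and without the 348 genes with unstable counts (this last setting was added after the data were seen, and it and the 6-library fit do not apply to any time). The ranges were 4509 to 4959 at 6 h against 0 h, 5911 to 6181 at 12 h, 4126 to 4691 at 24 h, 4471 to 4828 at 48 h, 3498 to 4643 for 12 against 6 h, 4763 to 5201 for 24 against 12 h, 1882 to 2563 for 48 against 24 h and 6885 to 7444 for any time. With the letter as a block they were 4568, 5955, 4126, 4471, 4192 and 4895 for the first 6 comparisons, 89.6% of the reported 2120 for 48 against 24 h, the largest loss, 6927 for any time, and 47 list calls. With a library left out, the counts were 4223 to 4611, 5671 to 5908, 3732 to 3945, 4072 to 4370, 3877 to 4225, 4542 to 4830, 1485 to 2095 and 6873 to 7116, and 45 to 47 list calls. A 2-fold threshold, which is stricter by construction, left 1367, 2748, 1112, 1404, 1260, 1622 and 439 genes in the 7 comparisons. Camera with an estimated correlation left 0 of 46 list calls, and fry, which does not compare a list with other genes, called 121 of 156. Of 46 list calls, 5 were lost without some library, each named in the report with its value. Named genes were run only with DESeq2, its size factors, the 50-count filter, the block and each library left out. Of their 207 results, 189 were called wherever these gave an adjusted p, 18 lost the call when some library was left out and 4 of these with the block; the cause was not tested. DESeq2 gave no adjusted p for 3. None reversed. With 3 libraries per time, changes under 2-fold and genes of high dispersion are the ones the depth and replication limit most. The alternatives meant for a table without counts were not run, since counts were present.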

Other observations

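Tests in this part chosen after the result was seen were camera on the functional classes of the table and both tests of genes with low counts at 12 h. Among the functional classes, cytoskeleton genes (90 tested) rose in 46, 50, 33 and 34 and fell in 9, 16, 7 and 9 at 6, 12, 24 and 48 h (camera adjusted p = 5e-04, 0.0032, 0.023 and 0.029). Intracellular trafficking genes (291 tested) rose in 109 and 131 and fell in 42 and 63 at 6 and 12 h (camera adjusted p = 0.014 at both). Coenzyme metabolism rose in 15 and 17 and fell in 40 and 47 at 6 and 12 h (camera adjusted p = 0.021 and 0.022). RNA processing rose in 48 and fell in 115 at 12 h and rose in 36 and fell in 97 at 48 h (camera adjusted p = 0.033 and 0.0079). Replication and repair rose in 85 and fell in 37 at 6 h (camera adjusted p = 0.0032). It was not called at 12 or 24 h (camera adjusted p = 0.81 and 0.87), unlike the list of DNA replication and the cell cycle. Cell cycle control was called up at 6 h and not at 12 or 24 h (camera adjusted p = 0.014, 0.11 and 0.59). Translation was not called at 6 or 12 h (camera adjusted p = 0.81 and 0.56). It was called up at 24 h and down at 48 h (camera adjusted p = 0.012 and 0.0079). With an estimated correlation, the adjusted p of these calls lay between 0.28 and 0.32.

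Some lists that camera did not call against 0 h at any time held strongly changed members. Endoglucanase 15 (NO03G05340), which cleaves glucans, rose at 12 h from 17.4 ± 1.48 to 219.9 ± 25.5 CPM, and endoglucanase NO08G02410 fell from 990.8 ± 43.3 to 201.7 ± 24.1 CPM. Of the 41 glucan and trehalose genes, 12 rose and 19 fell at 12 h (14 and 19 adjusted over the list alone). Aspartic proteinase Asp1 (NO13G01470) rose from 3.12 ± 0.671 to 44.8 ± 3.56 CPM, and of 69 genes of autophagy and vacuolar proteolysis 18 rose and 26 fell (18 and 26 adjusted over the list alone). Glutaredoxin-C6 (NO24G01610) rose from 24.2 ± 1.63 to 155.2 ± 11.7 CPM, and of 54 antioxidant genes 12 rose and 27 fell (12 and 27 adjusted over the list alone). The vacuolar ATPase and proton pump list had 9 of 21 up and 5 down (9 and 5 adjusted over the list alone), the aminoacyl-tRNA synthetases 9 of 42 up and 17 down (9 and 17 adjusted over the list alone), the nucleases and nucleoside transporters 4 of 21 up and 6 down (4 and 6 adjusted over the list alone), and the inositol phosphate kinases 4 of 24 up and 9 down (4 and 9 adjusted over the list alone). Unlike these, the list written for organelle-encoded transcripts was called down by camera at 48 h. It matched nuclear loci by name, such as ChlH, so it does not measure organelle transcripts. At 48 h 9 of its 74 genes rose and 31 fell (9 and 33 adjusted over the list alone, camera adjusted p = 0.014, and adjusted p = 0.34 with an estimated correlation). The list for genes of other organisms had 4 tested members, of which 1 rose and 2 fell at 12 h (1 and 2 adjusted over the list alone), so it says little about contamination.

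For 348 tested genes, libraries of the same time ranged from fewer than 10 to at least 100 counts. A read assignment that switches between loci could give this. A locus within 2 places gained what was lost in 37.9% of 609 cases, against 30.4% for loci 100 places away, and a locus of the same description did so in 24.4% of the cases with such a locus, against 15.2% at random. Both shares were above their comparison but less than 2 times it, the limit written before the test. In most cases no such locus gained what was lost, which argues against either as the whole source. The comparison loci also met the criterion often, so the test cannot tell whether exchange gave part of the cases. Overlapping or unannotated loci were not tested and stay open, and no biological explanation was tested.

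Of the 3107 genes with the lowest mean counts, 715, 1029, 716 and 840 were higher and 444, 576, 342 and 342 lower at 6, 12, 24 and 48 h than at 0 h, with medians of 0.09, 0.18, 0.12 and 0.17, and of the 3107 with the highest, 924 were higher and 1435 lower at 12 h. Over all pairs of a library of 12 h and one of 0 h, the median of the low group was above that of all tested genes by at least 0.19, against at most 0.04 between libraries of the same time. A single factor per library leaves this difference unchanged, so the values argue against such scaling only for the rise relative to all tested genes. Background reads added to every locus could raise genes of low count. To bound them, 0.15 FPKM, the 10th percentile over all genes at 12 h, was taken from every gene at 12 h. The group's median, here from mean FPKM and not from the edgeR fit, fell from 0.15 to 0.04 (95% bootstrap interval -0.01 to 0.11). That interval holds 0 and also values close to the median before. The bound is loose, since genes below it cannot have gained that much. Of 10434 genes, 9671, 9609 and 9605 had a count in 12 h replicates a, b and c, so the others gained no reads there. These values argue against an equal addition of that size to every locus. A smaller or uneven background stays open at 12 h, and for the other times neither scaling nor background was tested. A wider switch of transcripts with time or deprivation also stays open, as an untested hypothesis.

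Other splits of the libraries were counted. For the 7 comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each, 1 split, the real one, reached the real count. The highest other split called 3, 1, 1 and 2 genes for 6, 12, 24 and 48 h against 0 h (4692, 6037, 4285 and 4597 real) and 3, 2 and 2 for 12 against 6 h, 24 against 12 h and 48 against 24 h (4358, 5010 and 2120 real). For genes changed at any time, 1 of 100 assignments, the real one, reached 7083, with 1360 the highest other, a share under 0.05. Any difference between times, also one of handling, could give this result. For the lists, 2 of 100 assignments reached 46 calls, with 46 the highest other, a share under 0.05. Another assignment thus called as many lists as the real one, so the count of list calls alone does not set the real times apart.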
